A study of Homo sapiens with 12 samples.

How the data were processed

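Gene expression was measured in MDA-MB-231 cells, an established human breast cancer line, on Illumina BeadChips, on which biotin-labelled RNA copies bind to probes carried by beads. Per the labels, the 12 arrays fell into 4 groups of 3: cells given a small interfering RNA (siRNA) against Sp1, cells given an siRNA against EZH2, and a separate group of cells given a control siRNA for each. The labels name the control siRNA of the siSp1 experiment A and that of the siEZH2 experiment B. Nothing in the labels says that arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

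The deposited raw tables, 1 per siRNA experiment, gave an intensity for each of 48803 probes on each of 6 arrays, on a linear scale with no normalization, exported with BeadStudio per the submitters' processing notes (version not given in the sources used here). The labels' protocols state isolation of total RNA, an amplification and biotin labelling by in vitro transcription, and no further step on the values. The authors' deposited series matrix held quantile-normalized log2 values of the same arrays, as judged from the values. For the siSp1 experiment these correlated by probe with the log2 raw intensities of the same array at r of 0.9997 or more across probes. For the siEZH2 experiment the correlation by probe was between -0.0025 and -0.0011. Each of those 48803 entries matched 1 raw probe by the ranks of its 6 values, within 2 places, under another probe name, and 0 matched under its own. The entry listed under the EZH2 probe was 6.595 ± 0.12 in controls and 6.663 ± 0.139 after siEZH2 (log2, SD, n = 3). The medians of the columns were 6.273 and 6.381. The series matrix therefore served as an alternative for siSp1 only, and the raw tables were used for all other results.

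Before the data were examined, the groups, the tests, 29 gene lists, the rule for named genes and the processing alternatives were fixed, except where a choice is said to have been made later. The plan used detection p-values, which were not used here because the tables hold none. Its stated fallback was followed. Background was corrected by normexp with an offset of 50, each table was quantile normalized over its own 6 arrays, and values were taken to log2. The offset pulls log2 changes of dim genes towards 0. In place of a detection p, a limit was set on each array at the background mode of the log2 intensities plus 2.33 standard deviations (SD) of the values below that mode, which corresponds to a one-sided tail of 0.01. This limit was chosen after the files were seen. It lay between 94.5 and 109.6 intensity units, and from 24.6% to 28.8% of probes were above it. Arrays give no counting depth, so the number of arrays and the signal over background limit the precision.

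Gene symbols are those of the deposited tables and can be old. Of 25235 symbols, 16013 are current RefSeq symbols, 2871 matched 1 current symbol as a synonym and 6351 were unmatched. Before this count, the symbols of 50 probes that had turned into dates were restored from the probe definitions. No symbol was given for 12646 probes, which were left out of gene counts. Of those, 238 were above the limit for siSp1 and 36 changed, and 366 were above it for siEZH2 and 45 changed, in a fit over all probes. Chromosomes are those in the tables, with no genome build named, so no coordinates are given.

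Each gene was represented by its brightest probe over the 12 arrays, and was tested where that probe was above the limit on at least 3 of the 6 arrays of a comparison. Each comparison was fitted with limma (lmFit and eBayes, version 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values are limma's unless another test is named. Fold changes and their standard errors (SE) come from the same fit. Where a group had no array above the limit, the fold is given as at least N-fold, from the brighter group's mean against the mean of the higher of the limit's normalized level and the probe's own value. The difference between both effects was fitted on all 12 arrays with 4 group means, so that the level of each table cancels. Overlaps were tested with Fisher's exact test over the genes tested in both comparisons.

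Gene lists were tested with limma's camera at a preset correlation of 0.01, which compares a list with the other genes, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The lists covered the Sp family and genes known to depend on it, ZBTB4 and the genes around it, both Polycomb complexes, genes known to be repressed by EZH2, HOX genes, the cell cycle, apoptosis, interferon and cytokine genes, epithelial, mesenchymal and matrix genes, YAP and TEAD targets, metabolism, stress, ribosomes, histones, chromatin, reference genes, and markers of luminal cells, leukocytes and fibroblasts. Lists with fewer than 3 genes tested were left out, which removed the fibroblast markers from both comparisons.

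The named genes are SP1, SP3, SP4, EZH2, ZBTB4, EED and SUZ12 whatever their values; per comparison the 10 that rose most and the 10 that fell most among called genes with all treated arrays on one side of all controls; from each list up to 4 members with the lowest adjusted p; the 5 in each direction with the largest difference between the effects; and the 5 in each direction called in both with the largest smaller change. Symbols that are only a locus number or an open reading frame were left out of the second part. Genes named beyond this rule were chosen after their values were seen, and not every gene that the rule picks is reported here.

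Alternatives were no background correction, median scaling, joint normalization of all arrays, the series matrix, no filter or a stricter one, the mean of a gene's probes, a shared spread, the replicate number as a block, an intensity trend with robust settings, array weights, both other list tests, a 1.5-fold threshold and each array left out. An offset of 16 was added after the data were seen.

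The fit was tested on simulated data with 200 planted genes per comparison, shared among the folds tested. Noise was drawn independently for each probe on normalized values, so correlation between genes, array effects and the normalization were not covered. The planted genes were also far fewer than the 1804 and 2147 called in the data, on which recovery depends. It recovered 37.3%, 85.1% and 100% of genes changed 1.5-, 2- and 4-fold for siSp1 (12604 probes, 10 false calls). The shares were 53.7%, 94.0% and 98.5% for siEZH2 (13476 probes, 10 false calls) and 23.9%, 80.6% and 98.5% for the difference (11764 probes, 12 false calls). Files were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.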

Results

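The series asked how EZH2, the histone H3 lysine 27 methyltransferase of Polycomb repressive complex PRC2, comes to be highly expressed in breast cancer, and its title links this to ZBTB4, a zinc finger repressor of transcription. The arrays compared MDA-MB-231 cells, a triple-negative breast cancer line, after depletion of the transcription factor Sp1 or of EZH2 by siRNA, each with its own control siRNA and 3 arrays per group. Mean intensity per array was 217.6 to 262.2 in the siSp1 experiment and 248.9 to 313.0 in the siEZH2 experiment. Log2 raw intensities of arrays of a group correlated across probes at r between 0.9795 and 0.9827 for siSp1 and between 0.9869 and 0.9887 for siEZH2, and arrays of different groups at 0.971 to 0.9753 and 0.9808 to 0.9827.

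After each siRNA the transcript it was made against was lower, and EZH2 fell after siSp1 as well. SP1 (chromosome 12, probe ILMN_1676010) went from an intensity of 141 ± 11.3 in controls to 89.0 ± 8.75 after siSp1 (SD, n = 3), where it was above the detection limit on 0 of 3 arrays, so that it was at least 1.36-fold lower (limma adjusted p = 0.00767). EZH2 (chromosome 7, probe ILMN_2364529) fell 2.47-fold after siEZH2 (log2 -1.30, SE 0.12, limma adjusted p = 0.000218), from 307 ± 27.7 to 122 ± 20.7, and 1.60-fold after siSp1 (log2 -0.68, SE 0.12, limma adjusted p = 0.00449), from 372 ± 37.2 to 206 ± 1.82. ZBTB4 (chromosome 17) rose after siSp1 (log2 0.59, SE 0.12, limma adjusted p = 0.00828), and its log2 change after siEZH2 was 0.27 (limma adjusted p = 0.116). SP1 itself differed by a log2 of -0.09 after siEZH2 (limma adjusted p = 0.653), a value that became 0.0102 without control replicate B.

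The remaining probes of these genes mostly moved the same way. The other EZH2 probes had log2 changes of -0.47 and -0.57 after siSp1 (limma adjusted p = 0.0152 and 0.0622). After siEZH2 the second of them had a log2 change of -0.68 (limma adjusted p = 0.00327), and the first was above the limit on 0 of 3 arrays, at a mean intensity of 86.4 against 162 in controls, so no fold is given. The other ZBTB4 probe rose by 0.80 after siSp1 (limma adjusted p = 0.00316) and by 0.44 after siEZH2 (limma adjusted p = 0.0211). EED, the PRC2 subunit that binds methylated histone H3, fell after siEZH2 at its brightest probe (log2 -0.56, SE 0.13, limma adjusted p = 0.0126). Another EED probe above the limit had a log2 change of 0.28, the mean over its probes was 0.0195, and without siEZH2 replicate 2 the adjusted p was 0.0518. SP3 had a log2 change of -0.41 after siSp1 (limma adjusted p = 0.0569) and of -0.00 after siEZH2, SP4 of -0.08 and -0.12, and SUZ12, a further PRC2 subunit, of 0.01 and 0.08, none past the threshold; the small values of SP3 and SP4 after siEZH2, SP4 after siSp1 and SUZ12 changed sign with the setting. The smallest p that an exact permutation test of 3 against 3 arrays allows is 0.1, and EZH2 reached it in both comparisons.

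**Figure D1:**
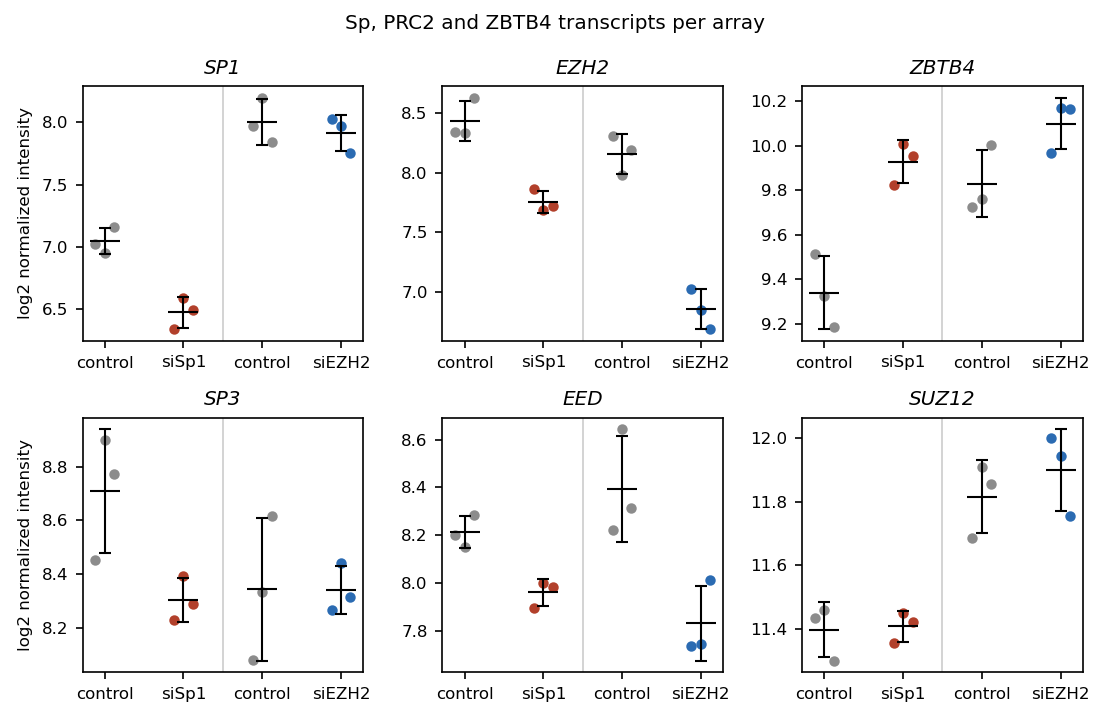
Normalized log2 intensity (vertical axis, not starting at 0) of the Sp and PRC2 genes and ZBTB4 on each array by group. Points are arrays and bars the mean ± SD (n = 3), with each experiment normalized on its own; EZH2 was lower after siSp1 (log2 change -0.68) and after siEZH2 (-1.30), and ZBTB4 higher after siSp1 (0.59).

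After siSp1, transcripts of cell division fell. Of 40 measured genes of mitosis and the G2/M transition 34 fell and 0 rose, with a median log2 change of -0.80 (n = 3 arrays per group). CENPA, the centromeric form of histone H3, fell 2.67-fold (log2 -1.42, SE 0.12), the mitotic kinesin KIF20A 2.53-fold, topoisomerase TOP2A 2.51-fold and cyclin CCNA2 2.46-fold (log2 -1.30), and NCAPG, a condensin subunit outside the list, fell 3.16-fold (log2 -1.66, SE 0.10). Of 27 genes induced by interferon 14 rose, led by IFI27 (4.53-fold, log2 2.18, SE 0.12), ISG15 (2.95-fold), OASL (2.73-fold) and IFI6 (2.62-fold), and 1, the RNA-activated kinase EIF2AK2, fell (log2 -0.67). This list passed camera at the preset correlation (adjusted p = 1.07e-05), but not with an estimated one (adjusted p = 0.0721 with an estimated correlation). The largest rise of any gene tested was that of HBB, which encodes beta globin, at 7.39-fold (log2 2.89, SE 0.11), and the largest fall that of PLS3, which encodes an actin-bundling plastin, at 5.12-fold (log2 -2.35, SE 0.17).

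In all, 1804 of 9704 genes changed after siSp1 (limma, adjusted p under 0.05), 912 higher and 892 lower, and 684 of them by at least 1.5-fold (319 higher, 365 lower). With median scaling in place of quantile normalization the split was 483 higher and 1442 lower, and the median log2 change of all tested genes -0.10 in place of 0.01. Without siSp1 replicate 1 the count was 1140, and without siSp1 replicate 3 it was 1170. Camera put the mitosis list at an adjusted p of 3.67e-23, and at 0.0112 with an estimated correlation. Adjusted over the list alone, 36 mitosis genes fell and 0 rose, and 17 interferon genes rose and 3 fell.

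Among the other genes that moved most after siSp1, the immediate-early transcription factors FOSB and FOS fell 3.29-fold and 3.01-fold, and NFKBIZ, a nuclear regulator of NF-kappaB target genes, fell 3.34-fold (log2 -1.74, SE 0.10). KISS1, which encodes the kisspeptin precursor, fell 2.74-fold and HNRPA2B1, an RNA-binding protein gene now named HNRNPA2B1, 2.55-fold. SERPINB2, a plasminogen activator inhibitor, rose 3.19-fold, RPL28, a ribosomal protein gene, 3.06-fold, PTPRR, a protein tyrosine phosphatase, 2.90-fold (log2 1.54, SE 0.12) and ZNF296, a zinc finger gene, 2.69-fold. ANGPTL4, an inhibitor of lipoprotein lipase, was above the limit on 0 control arrays and rose at least 2.33-fold. The limma adjusted p of these 10 genes was 0.000459 or lower, the value of HNRPA2B1. HBB stood among the fixed leukocyte and blood markers, of which 3 of 15 could be tested and 1, HBB itself, rose.

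Of the genes of DNA replication and the G1/S transition, 15 of 39 fell and 1 rose after siSp1, with a median log2 change of -0.20 (-0.33 with median scaling) and the same counts adjusted over the list alone. Thymidylate synthase TYMS (log2 -1.09), the helicase genes MCM5 (-0.98) and CDC45L (-0.88) and the ribonucleotide reductase subunit RRM1 (-0.64) fell, and cyclin E1, CCNE1, rose (1.01). The camera adjusted p was 0.000656, and the adjusted p was 0.285 with an estimated correlation. Of 13 YAP and TEAD targets 5 fell and 0 rose (median -0.36; 6 and 0 adjusted over the list alone), among them the ecto-nucleotidase NT5E (-1.07), the matricellular CYR61 (-0.58) and CRIM1 (-0.54). That list passed camera at 0.044, but its adjusted p was 0.285 with an estimated correlation, 0.0592 with median scaling, 0.053 with all arrays normalized together, 0.0568 with an offset of 16, 0.0754 without control replicate 2 and 0.0802 without siSp1 replicate 2.

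No other list passed camera after siSp1, although single members changed. Of 22 inflammatory cytokine genes 8 fell, among them CXCL2 (log2 -1.22), IL6 (-1.03), CXCL1 (-0.88) and CSF3 (-0.80), and 4 rose, IL24 (1.04), IL11 (0.88), CSF2 (0.84) and LIF (0.50), with a camera adjusted p of 0.0623 and counts of 10 and 5 adjusted over the list alone. Of 16 genes known to be repressed by EZH2, 1 rose, the forkhead gene FOXC1 (0.89), and 5 fell, IL6, IGFBP3 (-0.57), DKK1 (-0.56), FBXO32 (-0.50) and SLIT2 (-0.49), with 1 and 6 adjusted over the list alone and a camera adjusted p of 0.0965. The call of SLIT2 was lost without control replicate 2 (adjusted p = 0.0518) and without siSp1 replicate 2 (0.0531). Of 12 PRC1 genes 2 rose, the chromobox subunits CBX2 (1.16) and CBX6 (0.86), and 1 fell. CBX2 was not past the threshold as the mean of its probes.

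Adhesion, matrix and stress genes moved both ways after siSp1. The keratins KRT8 (log2 -0.64) and KRT18 (-0.63) fell among 18 epithelial genes (2 rose, 3 fell), where another KRT18 probe read 0.16 and KRT18 was not called as the mean of its probes. SNAI2, a repressor of epithelial genes, rose (0.78) among 13 mesenchymal genes (2 rose, 3 fell). PLAU, the urokinase gene, fell (-0.99), as did THBS1 (-0.63) and COL13A1 (-0.60), and MMP1 (0.83) and COL5A1 (0.72) rose among 23 matrix and protease genes (3 rose, 6 fell). DDIT4 (-1.03) and ADM (-0.67) fell and P4HA2 (0.62) rose among 30 hypoxia and glycolysis genes. TRIB3 fell (-0.80) and ASNS (0.52) and ATF4 (0.50) rose among 30 stress response genes (4 rose, 4 fell). The cyclin-dependent kinase inhibitor CDKN1A (0.67) and GADD45B (0.58) rose and BTG1 (-0.68) fell among 16 cell cycle inhibitors and p53 targets (4 rose, 2 fell). Other probes read 0.05 and 0.36 for P4HA2, 0.25 for ASNS and -0.29 for COL13A1, none called (limma adjusted p of 0.0834 or higher).

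The remaining lists gave few calls after siSp1. For the Sp family (4 tested) the count was 0 rose and 1 fell, the latter SP1, the target of the siRNA. For the genes around ZBTB4 (7), with SP1 among the fallen, it was 1 and 3, and for PRC2 (10) 0 and 2. For Sp-dependent growth genes (19) it was 1 and 4 and for apoptosis regulators (23) 3 and 3. For cholesterol synthesis (21) it was 2 and 1, for fatty acid synthesis (15) 2 and 0, for oxidative phosphorylation (34) 1 and 4, for ribosomal proteins (36) 2 and 0, and for HOX genes (7) 0 and 0. For histones (11) it was 2 and 0, for chromatin modifiers (20) 1 and 2, for reference genes (16) 1 and 1 and for luminal markers (5) 0 and 2. Adjusted over the list alone the Sp family had 0 and 3, the genes around ZBTB4 1 and 5, PRC1 3 and 1, epithelial genes 2 and 4, mesenchymal genes 2 and 5, matrix and protease genes 5 and 7 and stress response genes 5 and 6. Cholesterol synthesis had 0 and 1, fatty acid synthesis 4 and 1, ribosomal proteins 1 and 0, histones 2 and 1, luminal markers 1 and 3 and reference genes 0 and 0, and the other lists kept their counts. The median, the mean and the camera direction differed in sign for epithelial genes, cell cycle inhibitors and p53 targets, and chromatin modifiers. PHF19, a PRC2 accessory gene, fell (log2 -0.57), but not without control replicate 3 (adjusted p = 0.056), siSp1 replicate 1 (0.0638) or siSp1 replicate 3 (0.0551).

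**Figure D2:**
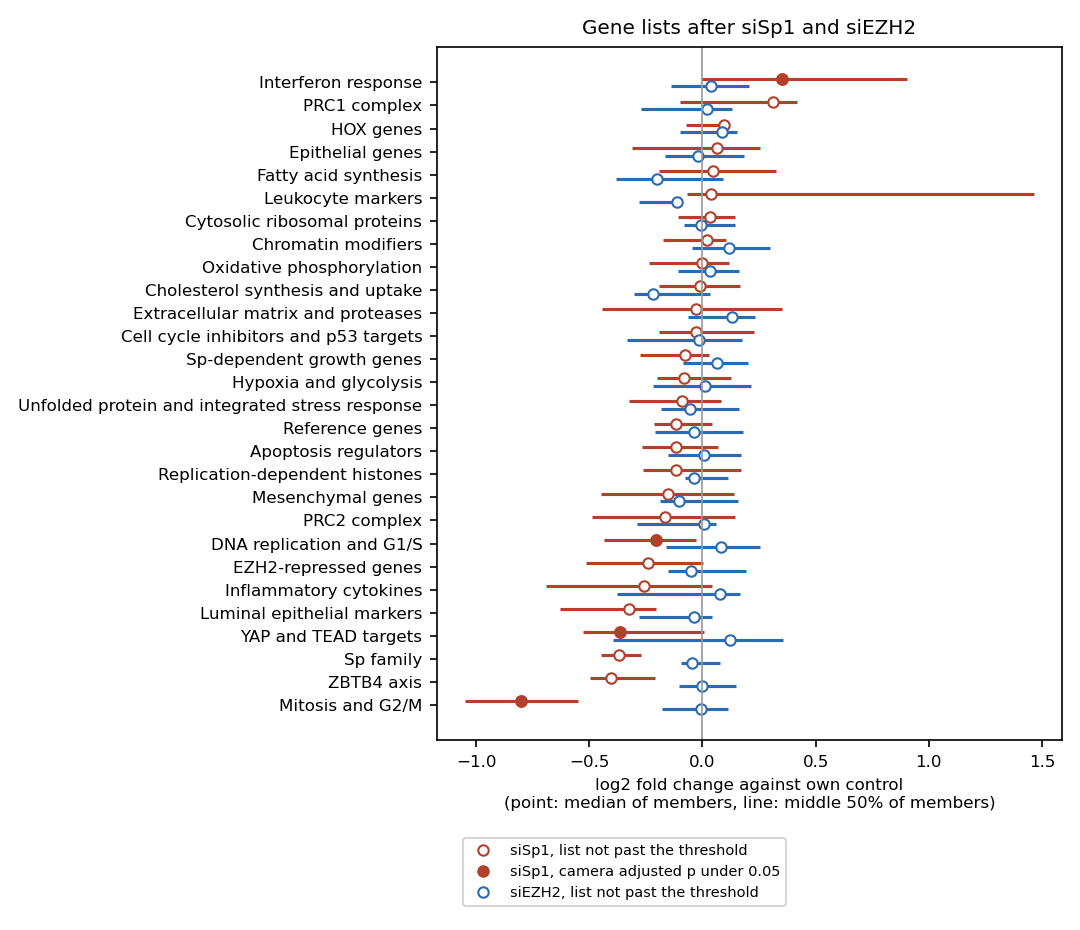
Median log2 fold change (point) and the middle 50% of members (line) of each fixed gene list after siSp1 and after siEZH2, against the own control. Filled points passed camera; the mitosis list lay at -0.80 and the interferon list at 0.35 after siSp1, and 0 lists passed after siEZH2.

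After siEZH2 single genes of many kinds changed and 0 of the fixed lists passed camera. The largest rise was that of the kinase gene MAP2K2 (2.21-fold, log2 1.15, SE 0.11, n = 3 arrays per group, limma adjusted p = 0.000224), and the largest fall that of MOCS2, which encodes both subunits of molybdopterin synthase (3.04-fold, log2 -1.61, SE 0.11, limma adjusted p = 3.83e-05). Of the genes known to be repressed by EZH2, 4 of 19 rose, the metalloproteinase inhibitors TIMP2 (log2 0.63) and TIMP3 (0.61), PEBP1, an inhibitor of RAF kinase (0.80), and IGFBP3 (0.67), and 1 fell, IL6 (-0.82). Their median was -0.05 (-0.13 with median scaling) and their mean 0.06, and adjusted over the list alone 4 rose and 3 fell. TIMP2 was not called as the mean of its probes, another of which read -0.09.

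In all, 2147 of 10346 genes changed after siEZH2 (limma, adjusted p under 0.05), 1194 higher and 953 lower, and 606 of them by at least 1.5-fold (332 higher, 274 lower). With median scaling the split was 509 higher and 1312 lower, and the median log2 change of all tested genes -0.08 in place of 0.02. The count was 1401 without siEZH2 replicate 2 and 1428 without siEZH2 replicate 3, and at 1.5-fold it was 936 with an offset of 16, and 401 with the mean of a gene's probes. Of 692 other probes of the called genes that were above the limit 500 (72.3%) moved the same way, against 483 of 551 (87.7%) for siSp1.

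GNG12, a G protein gamma subunit, fell 2.96-fold after siEZH2 (log2 -1.56, SE 0.12), IGFBP1, an insulin-like growth factor binding protein, 2.67-fold, and the mitochondrial carrier SLC25A24 2.62-fold. FAM18B2, now TVP23C, fell 2.55-fold, the elongation factor TCEA1 2.52-fold, ARL6IP6 2.37-fold, the depalmitoylating enzyme LYPLA1 2.34-fold, and NAMPT, which makes the precursor of NAD, 2.29-fold. POFUT1, which adds fucose to Notch, rose 2.17-fold (log2 1.12, SE 0.16), the inositol phosphatase INPP5A 2.16-fold, LMOD3, a leiomodin gene, 2.13-fold, and ZNF462, a zinc finger gene, 2.10-fold. GSTTP2, a glutathione transferase pseudogene, rose 2.12-fold, the DNA glycosylase MBD4, the interleukin 7 receptor IL7R and the aminopeptidase LRAP, now ERAP2, each 2.09-fold, and the acetylcholine receptor subunit CHRNA5 2.03-fold. The limma adjusted p of these genes was 0.00137 or lower, the value of POFUT1. Other probes of POFUT1 and CHRNA5 read -0.15 and -0.03, those of TCEA1, NAMPT and LYPLA1 -0.33, -0.21 and -0.12, and POFUT1 and GSTTP2 were not called as the mean of their probes.

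Of the fixed lists, 0 passed camera after siEZH2 and 0 passed with an estimated correlation, while 3644 single genes had an unadjusted p under 0.05. By fry, which asks whether the members move 1 way without setting them against other genes, 3 lists passed. Of 23 genes of cholesterol synthesis and uptake 4 fell, IDI1 (log2 -0.76), FDFT1 (-0.67), INSIG1 (-0.61) and SC5DL (-0.45), and HSD17B7 rose (0.83), with a median of -0.22 (-0.34 with median scaling), a camera adjusted p of 0.179 and a fry adjusted p of 0.00523. Another FDFT1 probe read -0.06 and another INSIG1 probe -0.24 (limma adjusted p = 0.756 and 0.196). Of 16 genes of fatty acid synthesis 5 fell, among them ACLY (-0.72), SCD (-0.64) and ME1 (-0.50), and 1 rose (median -0.20, or -0.31 with median scaling, fry adjusted p = 0.0422; 7 and 2 adjusted over the list alone). Of 26 matrix and protease genes 3 rose, TIMP2, TIMP3 and TNC (0.46), and 0 fell (fry adjusted p = 0.0378). TIMP2 and TNC were not called as the mean of their probes, and TNC not with median scaling.

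Cell cycle genes went both ways after siEZH2. Of 40 mitosis genes 3 rose, FOXM1 (log2 0.88), AURKB (0.50) and CENPF (0.31), and 4 fell, CDC2 (-0.78), now CDK1, MAD2L1 (-0.65), CDC25C (-0.64) and CENPA (-0.49). Other probes read -0.10 for MAD2L1 and -0.12 and -0.17 for CDC25C, while those of CDC2 and FOXM1 read -1.09 and 0.58. Of 39 DNA replication genes 7 rose and 5 fell. The inhibitors CDKN2C (-0.72), CDKN1B (-0.67), CDKN2D (-0.59) and CDKN1A (-0.35) fell among 18 cell cycle inhibitors and p53 targets, of which 2 rose. Of 31 interferon genes 5 rose and 1 fell (median 0.04, or -0.058 with median scaling), the 5 being OASL (0.73), IFIT3 (0.65), HERC6 (0.55), IFIT1 (0.54) and PARP14 (0.52). Other IFIT3 probes fell (-1.13 and -0.42), and as the mean of its probes IFIT3 was called lower (-0.30, adjusted p = 0.0387). OASL, IFIT1 and CDKN2C were not called as the mean of their probes, and IFIT1 not with median scaling (adjusted p = 0.0544). Of 23 inflammatory genes 6 fell, among them IL6, IL1B (-0.78) and CSF2 (-0.74), and 3 rose.

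The remaining lists after siEZH2 were as follows, with genes tested, risen and fallen: Sp family 4, 0 and 0, Sp-dependent growth genes 19, 1 and 1, genes around ZBTB4 7, 1 and 1, PRC2 11, 0 and 3, PRC1 13, 1 and 2, and HOX genes 8, 0 and 2. The PRC2 falls were those of EZH2, the target of the siRNA, of EED and of AEBP2. AEBP2 was not called without control replicate C (limma adjusted p = 0.0686), siEZH2 replicate 2 (0.0571) or siEZH2 replicate 3 (0.0577). EZH2 was also the fall among the genes around ZBTB4. Apoptosis regulators had 25, 2 and 1, epithelial genes 20, 3 and 0, with CLDN1, a tight junction gene, at 0.93, mesenchymal genes 16, 1 and 1, and YAP and TEAD targets 12, 2 and 4, with CRIM1 at -0.82. Hypoxia and glycolysis genes had 31, 2 and 4, stress response genes 28, 2 and 4, with XBP1 at -0.58, and oxidative phosphorylation genes 34, 2 and 3, with SDHD at -0.94. Ribosomal proteins had 36, 3 and 1, histones 11, 1 and 1, chromatin modifiers 20, 5 and 1, reference genes 16, 2 and 3, luminal markers 6, 0 and 1 and leukocyte markers 3, 0 and 1. Adjusted over the list alone the Sp family had 1 and 0, DNA replication 8 and 5, mitosis 2 and 4, cell cycle inhibitors and p53 targets 2 and 6, inflammatory genes 3 and 8, epithelial genes 2 and 0, mesenchymal genes 1 and 0 and YAP and TEAD targets 4 and 4. Hypoxia and glycolysis genes had 4 and 5, ribosomal proteins 2 and 1, histones 2 and 1, reference genes 4 and 3 and luminal markers 0 and 2, and the lists not named with such a count kept theirs. The median, the mean and the camera direction differed in sign for the Sp family, PRC1, PRC2, EZH2-repressed, HOX, apoptosis, inflammatory, epithelial, mesenchymal, hypoxia, oxidative phosphorylation and ribosomal protein lists.

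The change against the own control differed between siEZH2 and siSp1 for 2019 of 9233 genes tested in both (limma on 12 arrays, adjusted p under 0.05), the siEZH2 effect lying above the siSp1 effect for 1103 and below it for 916. NFKBIZ, which fell after siSp1 (log2 -1.74) and rose after siEZH2 (0.54), differed by 2.28 (SE 0.13), PLS3 by 2.03 (SE 0.20), KISS1 by 1.82, NCAPG by 1.81 and FOSB by 1.71. On the other side IFI27 differed by -2.42 (SE 0.15), FAM18B2, which rose after siSp1 (0.48) and fell after siEZH2 (-1.35), by -1.84, PTPRR by -1.64, the cytokine CSF2 (0.84 and -0.74) by -1.59 and WRB (0.61 and -0.92) by -1.53. The limma adjusted p of these 10 differences was 0.000453 or lower. Each siRNA was used in an experiment of its own with its own control siRNA, so siRNA and experiment cannot be told apart in these differences, and the controls themselves stood apart for FOSB, with an intensity of 1073 ± 52.4 in the siSp1 experiment and 212 ± 10.7 in the siEZH2 experiment (raw, SD, n = 3, tables not normalized together). NFKBIZ after siEZH2 was not called as the mean of its probes.

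The mitosis list differed by a median log2 of 0.87 between the experiments (siEZH2 effect minus siSp1 effect; camera adjusted p = 1.98e-13, and adjusted p = 0.00164 with an estimated correlation). For the interferon list the median was -0.36 (camera adjusted p = 0.000702, and adjusted p = 0.0255 with an estimated correlation). For DNA replication it was 0.32 (camera adjusted p = 0.00503, and adjusted p = 0.298 with an estimated correlation). Of the 27 lists tested for a difference these 3 passed camera.

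More genes moved the same way after both siRNAs than independent lists would share. Of 9233 genes 140 rose in both, against 107.8 for independent lists (odds ratio 1.41, 95% interval 1.15 to 1.71, Fisher's exact p = 0.00078), and 126 fell in both, against 85.7 (odds ratio 1.64, 1.33 to 2.01, Fisher's exact p = 4.96e-06). Opposite moves numbered 149, 59 that rose after siSp1 and fell after siEZH2 (odds ratio 0.654, 0.489 to 0.862) and 90 the other way (0.786, 0.619 to 0.988). Locus-number, open reading frame and clone symbols were left out of the ranks that follow. The largest shared rises were those of ZNF581 (log2 0.81 after siSp1 and 0.79 after siEZH2), the defensin DEFB103B (1.21 and 0.74), OASL (1.45 and 0.73), the phosphatase CDC25A (1.18 and 0.70) and CXXC5 (0.70 and 0.88). The largest shared falls were those of IL6 (-1.03 and -0.82), HNMT, which inactivates histamine (-0.79 and -0.80), the chemokine CXCL2 (-1.22 and -0.69), EZH2 (-0.68 and -1.30) and HSD17B11 (-0.68 and -0.73). Without siSp1 replicate 1, or without siEZH2 replicate 2, 174 genes moved the same way in place of 266. OASL and HNMT after siEZH2 were not called as the mean of their probes. Another CDC25A probe read 0.30 after siSp1 and 0.10 after siEZH2 (limma adjusted p = 0.113 and 0.596).

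Across the 9233 genes the log2 changes after both siRNAs correlated weakly, with a Pearson r of 0.103 and a Spearman rho of 0.102, genes not being independent replicates. The experiments had separate control arrays.

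**Figure D3:**
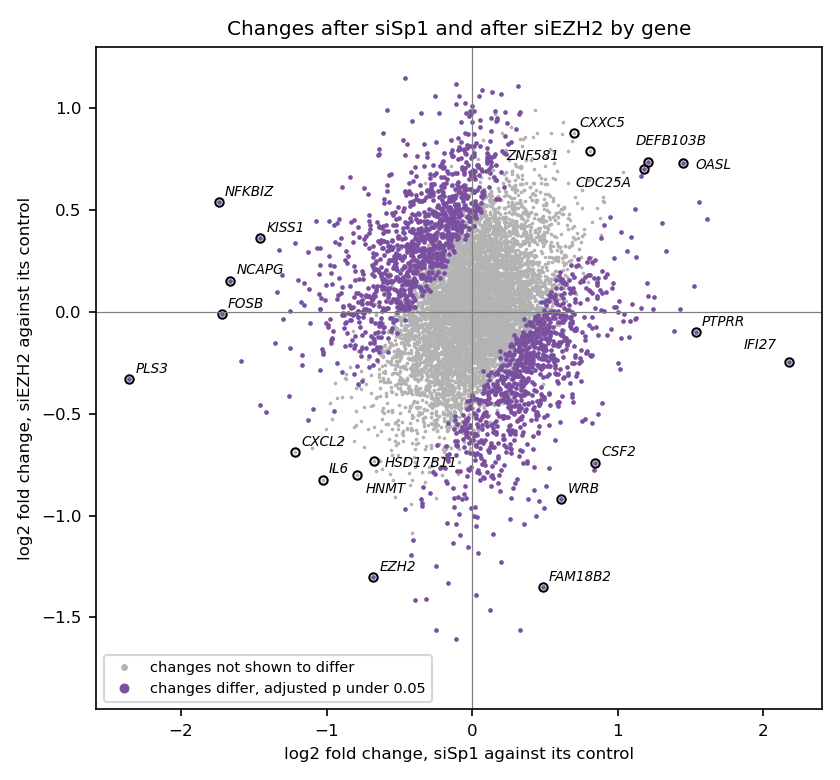
Log2 fold change after siSp1 (horizontal axis) and after siEZH2 (vertical axis) of each gene tested in both, each against its own control. Each point is a gene, and coloured points are the 2019 whose changes differed. The circled, named genes are those with the largest differences, such as NFKBIZ (2.28) and IFI27 (-2.42), and the largest shared changes, such as EZH2 (-0.68 and -1.30). Locus-number, open reading frame and clone symbols were left out of these ranks.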

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

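The tests weighed in this part were chosen after the results were seen, except the test within 10 classes of genes by brightness.

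The changes after siEZH2 and after siSp1, each against its own control, differed for 2019 genes (limma on 12 arrays), where siRNA and experiment cannot be told apart. Of 100 splits of the arrays, 2 gave as many, the real one included. The highest other, 2625, came from the split that turns the labels of 1 whole experiment and so tests the sum of both effects. Other splits that kept 1 experiment whole gave at most 434, and splits that mixed both experiments gave 0. Such splits ask whether either siRNA had an effect, not whether both effects were equal. They therefore cannot decide whether chance made the difference. For siSp1 and siEZH2 against their controls, 1 of 10 splits each, the real one, gave as many genes (1804 and 2147, with 0 as the highest other), and 10 splits are too few for a share under 0.05. Among genes not left out by symbol, the largest differences of the siEZH2 effect from the siSp1 effect were those of NFKBIZ (log2 2.28), PLS3 (2.03), KISS1 (1.82), NCAPG (1.81) and FOSB (1.71) on one side and IFI27 (-2.42), FAM18B2 (-1.84), PTPRR (-1.64), CSF2 (-1.59) and WRB (-1.53) on the other. Among lists, mitosis differed by a median of 0.87, DNA replication by 0.32 and interferon genes by -0.36, the second not past the threshold with an estimated correlation (adjusted p = 0.298).

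HBB showed the largest rise after siSp1, from an intensity of 207 ± 25.1 to 1345 ± 94.4 (SD, n = 3), and was above the limit on 0 arrays of the siEZH2 experiment. RNA from red cell precursors would bring the other abundant erythroid transcripts, but among 15 further erythroid genes (20 probes), alpha globin among them, the highest mean on the siSp1 arrays was 80.8, below the limit, which argues against that source; 1 gene, the gamma globin HBG1, was above the limit on 1 siSp1 array (80.8 ± 21.9 against 62.3 ± 8.4 in controls, SD, n = 3). A single aberrant array is argued against too, since the log2 change was at least 2.868 with any siSp1 array left out. What raised HBB stays open: an effect of lower Sp1 may be set beside an effect of this siRNA on other transcripts, and no second siRNA against Sp1 was analysed here.

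Of 27 interferon genes 14 rose after siSp1, and the list passed camera there, though not with an estimated correlation (adjusted p = 0.0721), and did not pass after siEZH2. A response to any transfected siRNA is argued against by the control siRNA given to the control cells, since such a response would cancel in the comparison. The median after siEZH2 was 0.0384 (-0.058 with median scaling), and the experiments differed (camera adjusted p = 0.0255 with an estimated correlation). Neither value bears on a response shared with the control siRNA. In the difference siRNA and experiment cannot be told apart. A response to the siSp1 duplex itself and an effect of lower Sp1 cannot be told apart, because these arrays hold 1 duplex against Sp1. Of 20 genes that encode interferons themselves, 1 was above the limit on all siSp1 arrays, and it was not called.

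Genes moved the same way after both siRNAs more often than independent lists would. Readier calls among bright genes would raise opposite moves too, but the higher odds ratio of those was 0.7855, and within 10 equal classes of genes by mean log2 value the lower common odds ratio of shared moves was still 1.2949 (95% interval 1.07 to 1.57), which argues against a trend with brightness as the whole cause. A candidate explanation is the fall of EZH2 after siSp1, which was 0.5203 of that after siEZH2 on the log2 scale. In proportion this predicts a median change of 0.2538 for the 2053 genes called after siEZH2 and tested in both, EZH2 itself left out. Their median change after siSp1, in the siEZH2 direction, was 0.0578 (95% bootstrap interval 0.0404 to 0.0721), and 57.7% moved that way. This is below the proportional prediction. The genes were picked by their siEZH2 changes, which picking tends to enlarge, so part of the shortfall may be built in. The interval also treats genes as independent. An effect that does not scale with EZH2, or that Sp1 loss partly offsets, cannot be told apart from other shared effects.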

How the results depend on the processing

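The offset of 16 was chosen after the data were seen; the other alternatives were planned. Of 5511 values of named genes and lists under alternatives, 5076 kept direction and side of the threshold, 319 fell short of it, 94 newly passed it and 22 changed sign (SP1 after siEZH2, counted apart, did too), and 134 of 213 called results lost no call under any alternative. Over alternatives on all arrays, 1377 to 2317 genes changed after siSp1 and 1821 to 2343 after siEZH2, 1527 to 2101 differed and 180 to 336 moved the same way. SP1 after siSp1 was called lower wherever it was tested, EZH2 after siSp1 lay between -0.81 and -0.57 and after siEZH2 between -1.63 and -0.96. With 1 array left out, which lowers the number of arrays, the ranges were 1140 to 1325 genes for siSp1, 1401 to 1683 for siEZH2, 1632 to 1900 for the difference and 174 to 218 for shared moves, 693 to 740 and 637 to 676 at 1.5-fold, -0.74 to -0.58 for EZH2 after siSp1, -1.39 to -1.23 for EZH2 and -0.17 to 0.0102 for SP1 after siEZH2, and 3 to 5 and 0 to 0 lists. For siEZH2 the 1.5-fold count was 936 with offset 16, which shrinks changes less, and 401 with the mean of a gene's probes. Lists passing for siSp1 and siEZH2 numbered 8 and 1 with no filter and 15 and 3 with fry, and 1 for siSp1 with an estimated correlation. Values that changed sign were, with median scaling, SUZ12 (-0.0921) and CD14 (-0.0232) after siSp1 and SUZ12 after siEZH2 (-0.0474); with the mean of probes, which adds probes that moved the other way, SP4 after siSp1 (0.0748) and, after siEZH2, EED (0.0195), SP4 (0.0102), SP3 (0.0992), BCL2L1 (-0.1918), MCL1 (-0.0987), IFIT3 (-0.2974), CD14 (0.0424) and LYZ (0.0341). With an array left out they were, after siSp1, CD14 (-0.0664 without control 1, range to 0.1204), SP4 (0.194 without control 3, range from -0.2934) and SUZ12 (-0.0388 without control 3, -0.0103 without siSp1 2, range to 0.0426), and, after siEZH2, SP1 (0.0102 without control B), SP4 (0.2003 without control A, 0.0136 without siEZH2 1, range from -0.3112), SP3 (0.1324 without control C, 0.0358 without siEZH2 1, 0.0125 without siEZH2 3, range from -0.1335) and KRT19 (0.0133 without siEZH2 3, range from -0.1881). Except where a reason is given, the cause was not tested. With the replicate number as a block, 1377 genes changed after siSp1, 1338 of them shared with the fit without it, and 1988 differed. Deviations of siSp1 and control arrays with the same number correlated across tested genes at -0.0502, -0.0208 and -0.0188. No shared deviation was thus seen, which cannot show whether such arrays were handled as pairs. The siEZH2 controls carry letters. The chip as a block was not run, since the columns name no chip, nor was the series matrix for siEZH2; normexp with offset 50 is the setting used throughout. Genes near background, such as SP1 after siSp1, have only a bound.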

Other observations

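The gene groups, the scan of symbols and the scan of chromosomes in this part were chosen after values had been seen.

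Immediate-early genes, which growth factor signals switch on within minutes, included FOSB and FOS, which were among the 10 genes that fell most after siSp1. Of 21 tested, 5 fell, FOSB (log2 -1.72), FOS (-1.59), EGR1 (-0.82), ATF3 (-0.44) and NR4A2 (-0.40), and 1 rose, KLF10 (0.69) (median -0.0018). After siEZH2, 3 of 20 rose and 0 fell. The control arrays of the experiments stood apart for these genes, with raw intensities in the siSp1 and siEZH2 controls of 8285 ± 151 and 399.8 ± 29.9 for EGR1, 2360 ± 170 and 158 ± 6.9 for FOS, 1073 ± 52.4 and 212 ± 10.7 for FOSB and 891 ± 25.5 and 142 ± 24.3 for ATF3 (SD, n = 3, tables not normalized together). Heterogeneous nuclear ribonucleoproteins bind and process messenger RNA precursors. Of the symbols of their genes, 9 of 23 fell, 0 rose and 14 were not called after siSp1 (median -0.20), and no list test was run. HNRNPC and HNRPC are a new and an old symbol of the same gene, as are HNRNPUL2 and HNRPUL2, so these genes were counted more than once. After siEZH2, 2 of 24 rose and 1 fell.

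The first letters of gene symbols were scanned with 816 tests for siSp1 and 860 for siEZH2. These tests, and those by chromosome, were Fisher's exact tests, one-sided for an excess of calls, with Benjamini-Hochberg adjustment. The scan of symbols gave 3 groups. After siSp1, 8 of 13 symbols beginning IFI rose (adjusted p = 0.00404) and 10 of 24 beginning HNR fell (adjusted p = 0.00988). The HNR symbols hold the same pairs of new and old symbols. After siEZH2, 94 of 679 symbols beginning LOC, which are provisional locus names, fell (adjusted p = 0.0248). By chromosome (48 tests per comparison), 57 of 403 genes on chromosome 9 rose after siSp1 (14.1% against 9.2% elsewhere). On chromosome 2, 78 of 610 fell (12.8% against 9%; Fisher's exact adjusted p = 0.0351 for both). After siEZH2, 101 of 628 genes on chromosome 19 and 53 of 288 on chromosome 20 rose (adjusted p = 0.00849 for both), and 74 of 565 on chromosome 3 (adjusted p = 0.0173) and 59 of 447 on chromosome 5 (adjusted p = 0.0339) fell. Each of these chromosomes leaned the same way after the other siRNA without passing. Chromosome 20 rose after siSp1 (14.6% against 9.3% elsewhere, Fisher's exact adjusted p = 0.0602). After siEZH2 chromosome 9 rose (15.3% against 11.4%, 0.0836) and chromosome 2 fell (12% against 9%, 0.074). The pattern is therefore not shown to be particular to 1 siRNA. Genes are not independent replicates, and these scans were not repeated under the alternatives.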
